A study of Caenorhabditis elegans with 2 samples.

How the data were processed

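Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans of a transgenic strain that carries F57A8.1 fused to a tag with enhanced green fluorescent protein. The strain carries a mutation of unc-119, and the transgene brings a working unc-119 copy as a marker, per the labels. Chromatin was fragmented by sonication to between 200 and 800 bp and precipitated with an antibody against GFP, per the labels. Both samples belong to 1 group, animals of both sexes at the young adult stage, 65 hours of age, and the labels number them as biological replicates 1 and 2. The design holds no second condition, so the comparisons are between peak positions and random positions, between classes of genes, and between the 2 replicates.

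The deposited files are 4 peak lists in coordinates of the ce11 build. The authors called peaks on each replicate against a control, and on both replicates pooled against a control, per the deposited file descriptions. The fourth list holds the peaks that passed a threshold on the irreproducible discovery rate (IDR), which compares the ranks of peaks between lists. It was derived by the authors from both replicates' alignments or peak lists. Which lists were ranked against each other could not be checked here. Passing did not require a high rank in each replicate: the thresholded peak ranked 129 by pooled signal ranked 228 in replicate 1 and 27389 in replicate 2. The peak caller, its version, the aligner, the filters, the scaling and what the control was, such as input chromatin of this strain or another, are not given in the sources used here. Each peak's signal value is the authors' measure of enrichment, and it was used here to rank or describe peaks within a list and for the correlation between replicates. The deposited −log10 q of each peak was used only to describe the lists. Read depth is unknown, and the signal values, their ranks and which peaks passed can depend on it; the Wilson intervals given for shares cover counting error only.

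The replicate and pooled lists each held 30000 peaks, so their length does not measure how much was bound. All 295 thresholded peaks had the same coordinates and signal as a peak of the pooled list and were its 295 highest by signal. Taking the top of the pooled list in place of the thresholded list was therefore void as an alternative, since it gave the identical set.

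Genes came from Ensembl release 115 on the WBcel235 assembly, the same sequence as ce11, with 19973 protein-coding genes on the 6 nuclear chromosomes. Names of tRNA, snRNA, snoRNA, miRNA and rRNA genes and the amino acid of each tRNA were taken from the RefSeq annotation of the same assembly by WormBase gene identifier. Coordinates are 1-based. A peak was represented by its summit. A summit was assigned to the protein-coding gene with the nearest annotated 5′ end within 2000 bp, which left 19966 assignable genes as the background. A summit counted as lying at a non-coding gene when it was within 250 bp of the gene's span, for tRNA, snRNA, snoRNA, miRNA precursor, rRNA and spliced-leader genes.

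Shares of summits were set against 10000 sets of random positions, drawn uniformly with the same number on each chromosome. These are called permutation tests of position below; they were two-sided, and their smallest possible p is 0.0001. Chromosomes were tested with exact two-sided binomial tests against their share of the length. Gene lists, fixed before the data were examined, were tested with Fisher's exact test, two-sided. All 2080 canonical 6-mers were tested with Fisher's exact test for presence within 50 bp of summits against equal windows centred 400 bp to either side. P-values were adjusted by the Benjamini-Hochberg method over the 6 chromosomes, the 6 non-coding classes, the 23 lists or the 2080 sequences. Replicate overlap was set against 1000 circular shifts (one-sided, smallest possible p 0.001), and the correlation of signal against 100000 permutations (two-sided, smallest possible p 1e-05). No covariates entered any test.

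The 23 lists, chosen by gene name, were cytosolic ribosomal proteins, collagens, vitellogenins, histones, major sperm proteins, chaperones, the proteasome, mitochondrial respiration, nuclear hormone receptors, homeobox genes, translation factors, splicing, germline, body muscle, pharynx, neuron, intestine, epidermis and seam, C-type lectins, cytochrome P450, basic helix-loop-helix factors, named zinc finger families, and argonaute and small RNA genes. Genes named in the text were fixed by rule: F57A8.1 and unc-119, the genes assigned to the 25 peaks with the highest signal (or the position where none was assigned), up to 4 assigned members of each list and up to 3 members of each non-coding class, by signal. Others are said to have been chosen after their values were seen.

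The alternatives tried were a stricter list of 147 peaks with the highest signal, the 295 highest peaks of each replicate's own list, the removal of peaks within 20 kb of F57A8.1 and unc-119, other distances and windows, and other random placements. No thresholded peak lay within 20 kb of those 2 genes, so their removal changed nothing for results on thresholded peaks. The functions were tested on simulated data: in a set of 295 positions with 40 planted at tRNA genes, 10 at ribosomal protein genes and a 6-mer planted in 60 windows, each planted feature was found and 0 other lists were called. Among 100 sets of 295 random positions the tests called the share near 5′ ends in 6, clustering in 4, tRNA genes in 2, any list in 3 and any 6-mer in 4. These sets followed the uniform placement that the tests of position assume, so they check the functions only. Summits held 49.7% GC against 35.9% beside them, a contrast the random sets were not given. Their count for 6-mers therefore does not measure false calls at the real summits. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.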

Results

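Binding of the tagged F57A8.1 protein was mapped in young adult worms by ChIP-seq with an antibody against GFP in 2 biological replicates. The thresholded list held 295 peaks covering 0.103 Mb, or 0.102% of the nuclear genome. Signal, in the authors' units, ran from 85.7 to 571 with a median of 105, and 163 of the peaks shared the highest −log10 q of the list, 2.51. Usual peak width was 356 bp, held by 282 peaks, and the 13 narrower ones all ranked among the 25 with the highest signal. Each replicate list held 30000 peaks, with signal between 14.4 and 256 in replicate 1 and between 16.2 and 319 in replicate 2.

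The strongest peaks lay at genes for short non-coding RNAs. Of the 25 peaks with the highest signal, 13 were within 250 bp of a snoRNA gene, whose products guide chemical modification of other RNAs, 3 of a tRNA gene, and 1 each of an snRNA, a miRNA precursor and a spliced-leader gene. The highest signal, 571, was at the snoRNA gene ZK994.7, on chromosome V from 8500579 to 8500645, with the summit at 8500560 in an intron of a protein-coding gene. It ranked first in both replicates, with signal 256 in replicate 1 and 319 in replicate 2. The next 2 peaks, with signal 484 and 408, were at C51F7.4 (V, 12303599 to 12303693) and T03F7.8 (V, 11314258 to 11314332), also snoRNA genes. The fourth, with signal 353, had its summit at 13463991 on chromosome I inside rpr-1 (13463955 to 13464207), the gene for the RNA of ribonuclease P, which trims the 5′ ends of tRNAs; this gene was named after its values were seen.

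A protein-coding gene was assigned to 13 of these 25 peaks. They were F55C5.17, W03C9.1, twk-5, sre-23, decr-1.2, egg-5, cec-4, rpl-15, kvs-3, nspc-17, M02F4.2, col-94 and C41C4.9, and a short non-coding gene of the 6 classes lay within 250 bp of the summit at each of these except rpl-15 and nspc-17. At kvs-3 the summit, at 9318265 on V, was 46 bp upstream of the 5′ end and inside the tRNA gene F44A2.t1. The other 12 had no protein-coding 5′ end within 2000 bp. Besides the peaks at ZK994.7, T03F7.8 and rpr-1, their summits were at 2514365 and 5707004 on I, 11474267 and 11026217 on IV, 9970318 on V, and 9743686, 11094219, 806655 and 9465889 on X.

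Across all 295 peaks, 141 (47.8%, 95% Wilson interval 42.2 to 53.5%) lay within 250 bp of a gene of the 6 non-coding classes, against 0.806% of random positions, a 59.3-fold excess (permutation test of position, p = 0.0001). tRNA genes accounted for 86 peaks (29.2%, interval 24.3 to 34.6%), 75.7 times the random share, and snoRNA genes for 42 (14.2%, interval 10.7 to 18.7%), 71.9 times. Another 6 peaks were at snRNA genes, a 43.3-fold excess, and 4 at spliced-leader genes, a 91.1-fold excess. For each of these 4 classes the Benjamini-Hochberg adjusted p over 6 classes was 0.00015, the smallest these permutations gave. In the 295 highest peaks of the single replicates, tRNA genes were near 23.7% in replicate 1 and 22.7% in replicate 2, and snoRNA genes near 12.5% and 15.3%. The smaller classes varied more, with 3 peaks at snRNA genes in replicate 1 (19.9-fold) and 7 in replicate 2 (50.7-fold), and 3 at spliced-leader genes in replicate 1 (62.5-fold) and 6 in replicate 2 (138.6-fold). Precursors of miRNAs were near 3 peaks (1.02%, permutation test of position, adjusted p = 0.0109). By the same permutation test this call did not hold in the stricter list (adjusted p = 0.244), in replicate 1 (0.678%, adjusted p = 0.0853) or within 500 bp (adjusted p = 0.056), and within 100 bp there was no such peak. None of the 20 annotated rRNA genes had a peak (upper limit of the interval 1.29% of peaks). Only 0.0156% of random positions lay near one, so this absence cannot be told from random placement.

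Among tRNA genes the highest signals were at F15G9.t1, a tRNA-Ala gene (X, 9743589 to 9743660, signal 220), F44A2.t1, also tRNA-Ala (V, 9318202 to 9318273, signal 187), and M02F4.t1, tRNA-Gly (X, 3036164 to 3036235, signal 173). Of 612 tRNA genes, 100 (16.3%, interval 13.6 to 19.5%) had a thresholded peak within 250 bp and 474 (77.5%) a peak of the pooled list. The share varied among 21 tRNA types (permutation test over 607 genes, p = 0.0476, chosen after the data were examined). That test took genes as independent, though 86 peaks accounted for the 100 genes. It held neither the chromosome nor the presence of identical copies fixed, so it does not settle whether the types differ. It ran from 5 of 13 tRNA-Cys, 11 of 34 tRNA-Ala and 11 of 34 tRNA-Thr genes to 0 of 27 tRNA-Gln genes. Of 346 snoRNA genes, 44 (12.7%) had a thresholded peak and 171 (49.4%) a pooled-list peak. The summit lay a median of 10.5 bp downstream of the tRNA 5′ end (quartiles -15.5 and 45.8 bp, negative being upstream), and a median of 28 bp upstream of the snoRNA 5′ end (quartiles -50 and 0 bp, where the median was -28).

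The snRNA genes with the highest signals were W05B2.8 (III, 10989679 to 10989780, signal 173), sup-6 (II, 12944803 to 12944967, signal 121) and H27M09.6 (I, 6847137 to 6847303, signal 107). Signal at W05B2.8 was uneven, ranking 9 in replicate 2 and 240 in replicate 1. At sup-6 it was more so, ranking 32 in replicate 2 and 5045 in replicate 1. The spliced-leader genes were led by sls-2.4 (I, 4172206 to 4172315, signal 214), sls-2.1 (II, 5844865 to 5844974, signal 147) and sls-2.2 (II, 5543598 to 5543707, signal 134); these genes encode the short leader that is joined to many worm messenger RNAs. The 3 miRNA precursors were mir-51 (IV, 11026013 to 11026112, signal 180), mir-80 (III, 8865270 to 8865367, signal 103) and mir-54 (X, 13144996 to 13145094, signal 95). Signal at mir-54 was 21.4 in replicate 1 and 80.1 in replicate 2.

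**Figure D1:**
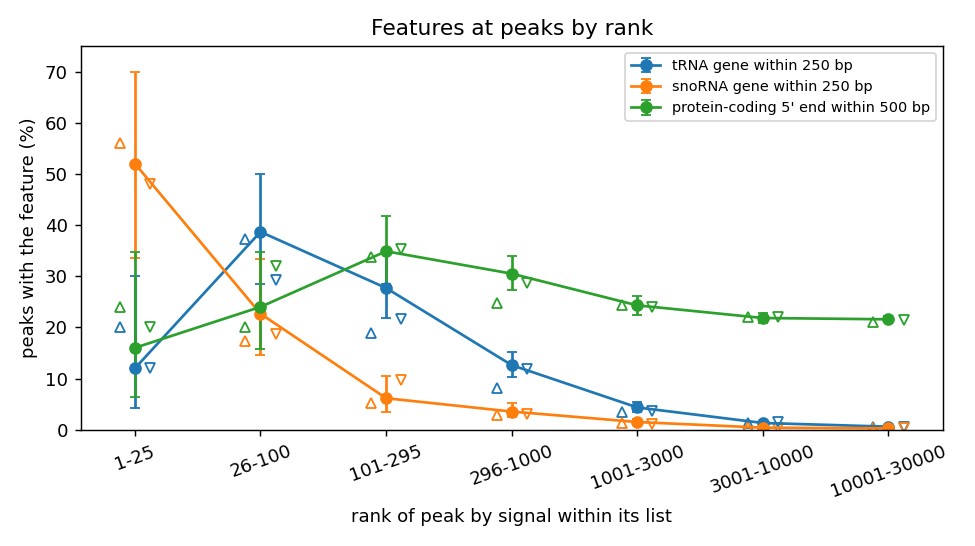
Percent of peaks with each feature, by rank of signal within a list; filled circles joined by lines are the pooled list with 95% Wilson intervals, and open triangles pointing up and down are replicates 1 and 2. Near snoRNA genes the share of pooled peaks goes from 52% at ranks 1 to 25 to 0.27% in the last interval, and near tRNA genes it is highest, 38.7%, at ranks 26 to 100.

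Genes for the translation machinery were over-represented among the 196 protein-coding genes assigned to peaks. Cytosolic ribosomal protein genes made up 11 of them, out of 82 in the background, where 0.805 would be drawn by chance (odds ratio 16.5, Fisher's exact test, Benjamini-Hochberg adjusted p = 1.08e-08). Their highest signals were 205 at rpl-15 (summit 323 bp upstream, IV, 654899), 165 at rpl-35 (465 bp upstream, III, 7854669) and 151 at rpl-3 (289 bp upstream, III, 3867565). The next was 140 at rps-13 (832 bp downstream, in a coding exon, III, 6374165). Summits at rps-16, rps-12, rps-1, rps-11 and rps-17, genes named after their values were seen, were also downstream in coding exons. Of the others, also named afterwards, the summit at rpl-41.2 was in a 3′ untranslated region and that at rpl-24.2 was 40 bp upstream. The peaks at rps-13 and rps-12 were within 250 bp of a snoRNA gene. At peaks away from the non-coding genes, 9 ribosomal protein genes were assigned (odds ratio 23.7, Fisher's exact test, adjusted p = 1.9e-08). Translation factors were assigned 4 of 39 members (odds ratio 11.7, Fisher's exact test, adjusted p = 0.00651): eif-3.G with signal 143, eif-2Bgamma with 97.9, iff-2 with 89.6 and eef-1A.2 with 88.9. The summit at eif-2Bgamma was within 250 bp of the snRNA gene sup-39. At eif-2Bgamma and eef-1A.2 replicate 2 had no summit within 100 bp. At iff-2 the signal was 63.9 in replicate 2 but 19.0 in replicate 1, equal to that replicate's list median of 19.0. At eif-3.G it was 55.8 in replicate 1 and 83.4 in replicate 2. The call of translation factors was lost in the top peaks of replicate 2 (Fisher's exact test, odds ratio 5.47, adjusted p = 0.272) and of replicate 1 (odds ratio 5.47, adjusted p = 0.309). It was also lost in the stricter list (Fisher's adjusted p = 0.949).

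The other 21 lists did not pass the threshold of Fisher's exact test adjusted over the 23 lists. Chaperones had 3 of 59 members at peaks (odds ratio 5.47, Fisher's adjusted p = 0.155), namely dnj-9, hsp-1 and dnj-13 with signals of 97, 88.2 and 87.0. They passed at the peaks away from non-coding genes (Fisher's adjusted p = 0.0341), a split chosen after the data were examined. Collagens had 4 of 175 (Fisher's adjusted p = 0.453), and col-94, with signal 173, col-85, with 102, and col-185, with 86.2, had a non-coding gene at the summit while col-120, with 88.6, did not. Germline genes had 2 of 54 (Fisher's adjusted p = 0.453), egg-5 with signal 214 and glh-1 with 111, and passed in the top peaks of replicate 1 alone, with 4 members (adjusted p = 0.0227). Neuronal genes had 3 of 167 (Fisher's adjusted p = 0.866), ins-39 with signal 144, nlp-76 with 135 and ins-13 with 134. The proteasome had 1 of 33 (pbs-6, Fisher's adjusted p = 0.914), mitochondrial respiration 1 of 43 (cox-5B, adjusted p = 0.995) and intestine 1 of 50 (ftn-1, adjusted p = 0.996). With an adjusted p of 1, histones had 1 of 72 (his-59), nuclear hormone receptors 1 of 274 (nhr-255), pharynx 1 of 86 (pqn-71), epidermis and seam 1 of 99 (wrt-3), C-type lectins 1 of 240 (clec-126) and cytochrome P450 1 of 74 (cyp-43A1). No member was assigned for vitellogenins, major sperm proteins, homeobox genes, splicing, body muscle, basic helix-loop-helix factors, named zinc finger families, or argonaute and small RNA genes.

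Summits lay within 500 bp of a protein-coding 5′ end at 90 of 295 peaks (30.5%, interval 25.5 to 36.0%), against 18.2% of random positions (permutation test of position, p = 0.0001). In the single replicates the share was 29.5% and 33.2%. Of the 147 peaks with the highest signal 21.1% were there, against 18% of random positions, which missed the threshold (permutation p = 0.337). Among the 154 peaks away from the 6 non-coding classes, 65 (42.2%, interval 34.7 to 50.1%) were within 500 bp of a 5′ end (permutation p = 0.0001). By annotation, 156 summits (52.9%) were between protein-coding genes against 37.8% of random positions, 94 (31.9%) in introns against 33.2%, 33 (11.2%) in coding exons against 24.2%, and 6 each in 5′ and 3′ untranslated regions. After adjustment over these 5 locations the excess between genes and the deficit in coding exons each had a permutation p = 0.00025.

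The X chromosome held 84 peaks, 28.5% of the list (interval 23.6 to 33.9%), while X makes up 17.7% of the nuclear length (exact binomial test, Benjamini-Hochberg adjusted p = 3.28e-05). In the single replicates X held 24.4% and 28.1% of the top peaks. By the same exact test, chromosome V held 42 (14.2% against 20.9% by length, adjusted p = 0.0123) and IV held 35 (11.9% against 17.4%, adjusted p = 0.0222). The deficit on V was not called by that exact test in replicate 1 (18.3%, adjusted p = 0.473) or in the stricter list of 147 peaks, where the share was 14.3% (adjusted p = 0.107), and that on IV in neither replicate alone, with 12.9% in replicate 1 and 13.2% in replicate 2 (adjusted p = 0.115 and 0.11). Chromosomes I, II and III held 39, 50 and 45 peaks (adjusted p = 0.447 each). tRNA genes are themselves unevenly spread, with 276 of 612 on X, and of the 209 peaks not near a tRNA gene 34 (16.3%) were on X (exact binomial p = 0.651, a split chosen after the data were examined).

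**Figure D2:**
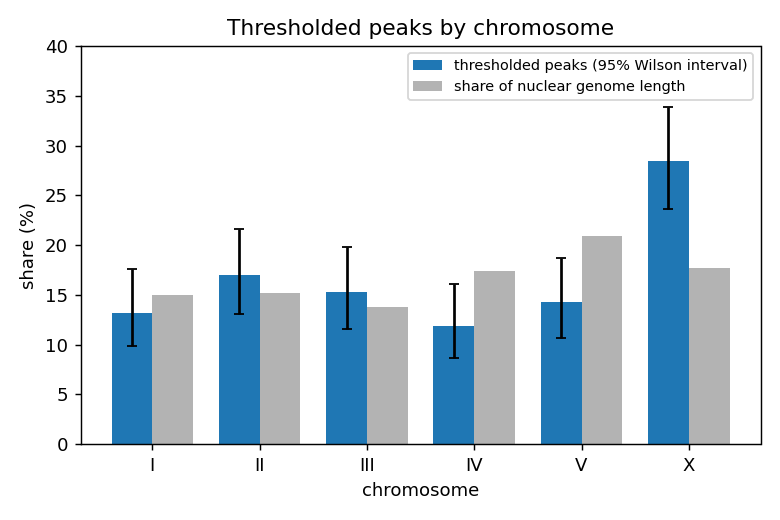
Share of the 295 thresholded peaks on each chromosome, with 95% Wilson intervals, beside the chromosome's share of nuclear genome length. X stands at 28.5% of peaks against 17.7% of length, and V at 14.2% against 20.9%.

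On the autosomes, 95 of 211 summits (45%, interval 38.5 to 51.8%) were in the middle one of 3 equal parts of their chromosome, against 33.4% of random positions (permutation p = 0.0005). Replicate 1 alone gave 47.1% (permutation p = 0.0001), and replicate 2 alone 39.2%, which missed the threshold (p = 0.0793). Peaks were mostly isolated, since 9 (3.05%) had another summit within 2000 bp against 1.29% at random (permutation p = 0.0436). The 9 included the peaks ranked 189 and 216, whose intervals overlap at rps-16 and may mark a single site. In the top peaks of the single replicates the share was 4.75% in replicate 1 (permutation p = 0.0021) and 4.07% in replicate 2 (permutation p = 0.0094), and within 5 kb it was 7.12% (permutation p = 0.0084). The excess rests on few peaks and was lost at 1 kb (1.36%, permutation p = 0.247) and in the 147 strongest peaks, of which 0 had such a neighbour.

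Summits were richer in G and C than the sequence beside them and held some short sequences far more often. Of 2080 canonical 6-mers, 322 were more frequent within 50 bp of summits than in windows 400 bp away and 190 were less frequent (Fisher's exact test, adjusted p at or below 0.05). The lowest p of all was for AAAAAA, in 12.9% of summit windows and 41.2% of those beside (Fisher's adjusted p = 1.44e-15). The sequences with the lowest p among those more frequent were GAACCC (14.2% against 0.847%, Fisher's adjusted p = 2.14e-13) and AGAGCG (16.9% against 1.86%, adjusted p = 3.55e-13), followed by ACGCAG (13.9% against 1.19%, adjusted p = 7.23e-12). In single replicates the differences were smaller: the odds ratio of GAACCC, 19.4 in the thresholded list, was 6.57 in replicate 1 and 7.12 in replicate 2, that of AGAGCG 10.7 against 6.01 and 5.75, and that of ACGCAG 13.4 against 4.07 and 10.5. AAAAAA was in 16.9% of summit windows of replicate 1 and 35.8% of those beside. GC content was 49.7% at summits and 35.9% beside them, and no test corrected for it. GAACCC was in 30.2% of windows at peaks near a tRNA gene and in 21.4% at those near a snoRNA gene and no tRNA gene. At peaks away from all 6 classes, with fewer windows, it was in 3.9% against 0.974% beside and was not called (Fisher's adjusted p = 0.299). AGAGCG was in 7.79% of windows there against 1.3% beside and was still called (Fisher's adjusted p = 0.0183). ACGCAG was in 16.9% of windows at these peaks and in 0.974% of the windows beside them. Whether GAACCC and AGAGCG mark more than the sequence of the non-coding genes themselves was not tested. The number of sequences called depended on the windows and the list, being 168 more frequent within 25 bp of the summit, 184 in the stricter list, and 72 at the peaks away from non-coding genes.

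The replicates shared a larger part of their strongest peaks than of longer lists. Of the 295 highest peaks of replicate 1, 107 (36.3%, interval 31.0 to 41.9%) had a summit within 100 bp of one of the 295 highest of replicate 2, against a mean of 0.0627% under circular shifts (one-sided permutation by circular shifts, p = 0.001, the smallest possible). At 147 peaks per list the share was 44.9%, at 590 it was 27.3% and at 1475 it was 19.3%. Both replicates had a summit of their own within 100 bp, among all 30000 peaks of each list, at 274 of the 295 thresholded peaks. A summit among a replicate's own 295 highest peaks was there for 179 thresholded peaks in replicate 1 and 192 in replicate 2. Across these 274 peaks, which are not independent replicates, the signal values had Pearson r = 0.721 (permutation p = 1e-05) and Spearman rho = 0.209 (permutation p = 0.0007). Without the 2 peaks farthest from the median of replicate 1, r was 0.57 and rho 0.191. Over the 25 strongest peaks r was 0.9 and rho 0.583, and over the other 249 r was 0.0147 (permutation p = 0.819) and rho was -0.0270 (permutation p = 0.67). The peaks were selected by the signal of both replicates pooled, and among the 249 this lowers the correlation by itself, so the values do not show whether the replicates differ there.

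**Figure D3:**
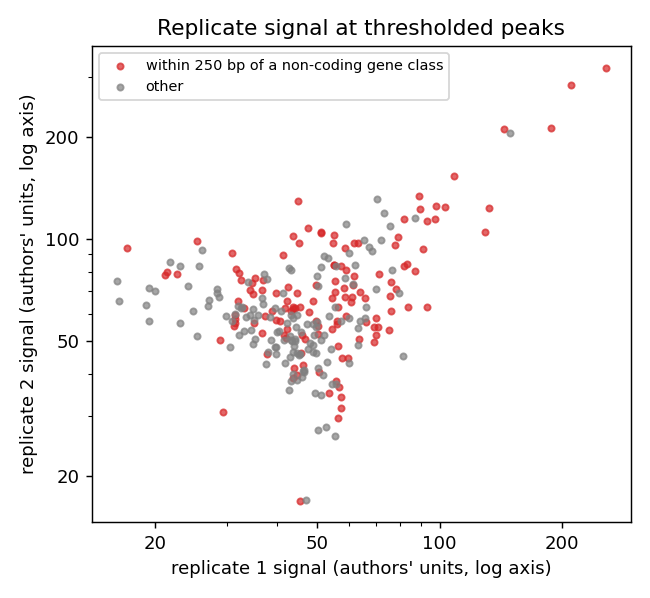
Signal of replicate 1 (horizontal) and replicate 2 (vertical), both in the authors' units on log axes, at the 274 thresholded peaks with a summit of both replicates within 100 bp. Red points are within 250 bp of a gene of the 6 non-coding classes; the points with the highest signal lie along a rising line and the rest form a cloud.

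The strain carries added copies of F57A8.1 and unc-119, so both loci were examined for signal from the transgene. No thresholded peak lay within 20 kb of F57A8.1 (V, 10037340 to 10048726) or unc-119 (III, 10902641 to 10908935), while 1 of the 295 highest peaks of replicate 1, at rank 207, lay near F57A8.1. The longer pooled list had 30 peaks within 20 kb of F57A8.1, more than at 99.5% of protein-coding genes, whose median was 13, and the best of them ranked 496. Since the window grows with the gene's length, the count per kb was also ranked, a choice made after the data were examined: it was above 98.5% of genes within 20 kb and above 92% within 10 kb. Each replicate list also had 30 there, above 99.8% and 99.6% of genes. Around unc-119 the pooled list had 5 peaks, more than at 5.88% of genes, with a best rank of 1068. In the replicate lists unc-119 had 10, above 21.7% of genes, in replicate 1 and 7, above 10%, in replicate 2. Peak lists carry no read counts, so copy number at either locus was not measured.

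**Figure D4:**
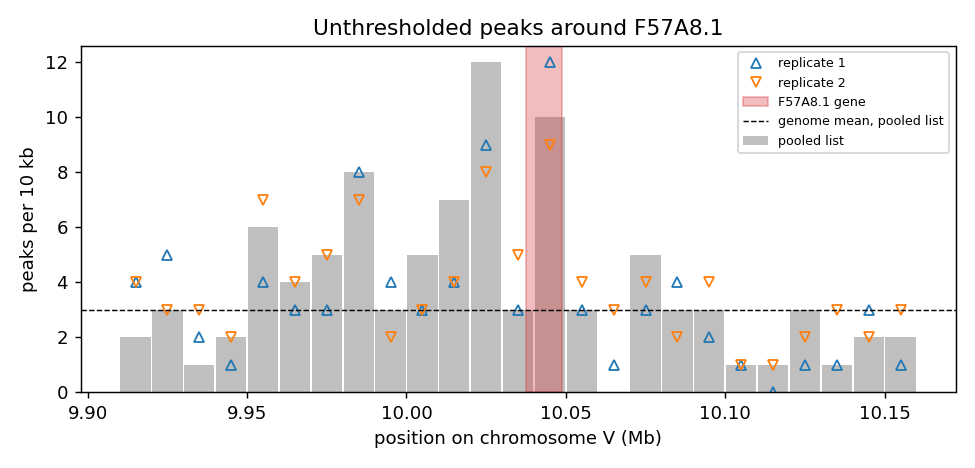
Peaks per 10 kb along chromosome V around F57A8.1 (shaded). Grey bars are the pooled list, open triangles the replicates, and the dashed line is the genome mean of the pooled list, 2.99 peaks per 10 kb; the tallest pooled bar, of 12 peaks, lies upstream of the gene, from 10020001 to 10030000.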

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

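The tests of extra copies at F57A8.1, of identical against single-copy tRNA genes, of X among peaks near tRNA genes, of weak peaks on X and of the recruitment sequence were chosen only after the result was seen, and the lists of abundant transcripts were picked with their values at thresholded peaks known. The design holds 1 group, so no biological explanation was tested against the technical ones.

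The first pattern is the concentration of peaks at tRNA and snoRNA genes, which was also seen among weaker peaks, outside the thresholded list that the tests of these genes used. Of the 705 pooled-list peaks ranked from 296 to 1000, 18.3% (Wilson interval 15.6 to 21.3%) were within 250 bp of a gene of the 6 non-coding classes. Reads shared between exactly identical gene copies are argued against as the whole cause. The 143 tRNA genes whose sequence occurs once were still near 12 summits, 42.9 times as often as random positions (permutation p = 0.0001), and no 2 snoRNA genes had the same sequence. Genes that differ by a few bases were not set apart and the filter on reads is unknown, so sharing between such genes stays open. Identical copies may still add to the concentration, since 18.6% of tRNA genes with them had a peak against 9.09% of the others (Fisher's exact p = 0.00654, genes taken as independent). What stays open is that any immunoprecipitation may enrich open, heavily transcribed loci. This was examined at pooled-list peaks ranked from 296 to 1000 away from the non-coding genes. There 5 lists of often abundant transcripts with no role in translation had together an odds ratio of 3.76 (22 of 327 genes, interval 2.29 to 5.88, Fisher's exact p = 5.91e-07). Collagens gave 17 of the 22 and vitellogenins 0, and histones, mitochondrial respiration and body muscle missed the threshold alone (Fisher's exact p = 0.654, 0.574 and 0.123). Cytosolic ribosomal protein genes had 14 of 82 at these peaks (odds ratio 10.6, interval 5.47 to 19.3). These lists hold protein-coding genes, so their values cannot decide the question for tRNA and snoRNA genes. No peak list from an unrelated antibody or an untagged strain was used here.

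The second pattern is the excess of peaks on X. A tilt of all peak calls toward X is argued against as the whole cause in the pooled list and in replicate 2, but not in replicate 1. Of pooled-list peaks ranked after 10000, 21.4% were on X (interval 20.8 to 22%). That is under the interval of the thresholded list (23.6 to 33.9%), though above the 17.7% given by length. In replicate 2 the interval of such weak peaks, 21.4 to 22.5%, was under that of its 295 highest peaks, 23.3 to 33.5%. In replicate 1 the 2 intervals overlapped, 19.2 to 20.3% against 19.9 to 29.6%. The density of tRNA genes on X remains a candidate explanation for the excess over length, which was not seen away from tRNA genes. Of the peaks not near a tRNA gene, 16.3% were on X (interval 11.9 to 21.9%), against 17.7% by length. Density alone is argued against for the peaks near tRNA genes, of which 58.1% were on X (interval 47.6 to 68.0%) against 45.1% of tRNA genes (exact binomial p = 0.0169). Whether recruitment sites of the dosage compensation complex, which lowers X expression in hermaphrodites, add to the excess stays open, since of the peaks away from the non-coding classes 20.8% were on X (interval 15.1 to 27.9%, exact binomial p = 0.341); the sequence tested was picked once related 6-mers had been seen at these same peaks, so its p is not independent of that choice. The 12-base sequence TCGCGCAGGGAG known from such sites, with up to 2 mismatches, was within 100 bp of the summit at 12 of the 32 X peaks away from the non-coding classes (37.5%, interval 22.9 to 54.7%) and at 1 of 122 such autosomal peaks (0.82%, Fisher's exact p = 1.07e-08).

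The third pattern is the number of weak peaks near F57A8.1, 30 in the pooled list within 20 kb, a locus with no thresholded peak. Extra copies carried by the transgene and a peak-rich stretch of chromosome V cannot be told apart here, because density within 20 kb was 1.62 times that 30 to 80 kb away, with an interval from 0.965 to 2.71 (exact binomial p = 0.0517) that leaves room for both. The value was first taken as bearing the peak-rich stretch out, because the p missed the threshold; the stricter reading used here, that the interval's upper end must lie below 2, was set after the value was seen. Around unc-119, the marker's gene, the count was above 5.88% of genes in the pooled list, 21.7% in replicate 1 and 10% in replicate 2, but how much worm sequence the marker holds is not given in the sources used here. Nor is the control, which would offset extra copies if it came from the same strain.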

How the results depend on the processing

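Alternatives limited to peaks ranked after 25 or away from non-coding genes, and peaks per kb at the transgene's loci, were chosen after seeing the data. Leaving out the transgene's loci, for thresholded peaks, and taking the top of the pooled list were void, since the sets were identical, and their 41 values are not counted here. Of the other 125 alternative values, 45 for the main value of a comparison and 52 others counted as kept. They kept their direction and their side of the threshold, or moved by less than their spread. Numbers of lists and of sequences counted as kept within a fixed ratio of the main number, whichever members they held. The 442 sequences more frequent with windows of 100 bp, in place of 322, were kept by that rule. The replicate overlap (19.3 to 44.9%), the X share (24.4 to 36.1%) and the share at non-coding genes (39.0 to 65.3%) were kept under every alternative counted. In the 147 strongest peaks the share near 5′ ends fell to 21.1%, 1 list passed the threshold in place of 2, 184 sequences were more frequent in place of 322, with fewer windows tested, and the clustered share was 0, under the random 0.712%. With 1 kb in place of 2 kb the clustered share was 1.36%, and with windows of 25 bp 168 sequences were more frequent. With single replicates, the number of lists past the threshold ran from 1 to 2 (replicate 1 alone called germline in place of translation factors), the share of autosomal peaks in chromosome centres from 39.2 to 47.1%, and the top peaks within 20 kb of the transgene's loci from 0 to 1. The share near miRNA precursors within 100 bp was 0, below random. Spearman's rho between replicates was -0.0270 for peaks ranked after 25, where selection on pooled signal lowers it by construction, and there were 72 more frequent sequences at peaks away from non-coding genes. Except where the smaller number of peaks or windows shows it, the cause was not tested. Read depth is unknown, so what it limits cannot be stated. No paired analysis was possible because there is 1 group.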

Other observations

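All tests in this part were chosen after the data were examined, and none was weighed against a control precipitation.

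Of 8 genes for other short RNAs, named after their values were seen, 2 were at thresholded peaks, and no test was run on this count. The ribonuclease P RNA gene rpr-1 ranked 4 in the pooled list with signal 353, and mrpr-1, for the related ribonuclease MRP RNA, ranked 132 with signal 107. The best peak at the Y RNA gene yrn-1 ranked 15527. At the 5 genes for signal recognition particle RNA the best pooled-list peaks ranked 399 (srpr-1.1), 3021 (srpr-3), 4341 (srpr-2.1), 9351 (srpr-2.2) and 22285 (srpr-1.2).

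A single 6-mer was counted at snoRNA genes because it was already more frequent at these summits, so the counts are not independent of that choice. GTTCGA, a part of the internal promoter element called the B box of tRNA genes, was within 50 bp of 16 of the 44 snoRNA genes with a peak (36.4%) and of 37 of the 302 without (12.3%, odds ratio 4.09, Fisher's exact p = 0.000172). At summits near a snoRNA gene and no tRNA gene it was in 13 of 42 windows (31.0%) against 3.57% of those beside. At peaks away from the 6 classes it was in 5.19% of windows and 4.22% of those beside (Fisher's p = 0.641). Of the snoRNA genes with a peak 45.5% lay inside a protein-coding gene on the same strand and of those without 54.3%, a difference that missed the threshold (Fisher's p = 0.332).

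A tRNA gene on X had a thresholded peak more often than one on an autosome, 59 of 276 (21.4%) against 41 of 336 (12.2%, odds ratio 1.96, Fisher's exact p = 0.0029). Among tRNA genes with identical copies the odds ratio was 1.91 (Fisher's p = 0.0086), and among single-copy genes it was 1.87 with few peaks (7 of 57 against 6 of 86, p = 0.374). These tests took genes as independent, though the 59 genes on X shared 50 peaks. Nor did they allow for the share of weak pooled-list peaks on X, 21.4% against 17.7% by length.

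The recruitment sequence found at X peaks away from the non-coding classes was at 1 of the 52 X peaks near them (1.92%), and in 3.13% of the windows 400 bp beside the former.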
